A study of Rattus norvegicus with 3 samples.

How the data were processed

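Motor cortex was taken from 3 untreated male Sprague-Dawley rats, and 1 mRNA library per animal was sequenced. Per the labels' protocols, total RNA was checked for integrity, purified with a DNase step, enriched for mRNA, fragmented and converted to a library by cDNA synthesis, end repair and ligation. The kit's strandedness, the read length and the annotation release are not given in the sources used here. HISAT2 2.0.4, a spliced aligner, StringTie 1.3.0, a transcript assembler and quantifier, and the rat build Rnor_6.0 are named per the submitters' processing notes, without role or order. The deposited FPKM values were made by the authors from fragments counted per gene and normalized, with a Perl script for the last step, per the labels. Each animal has 1 table with 1 FPKM value for each of 30957 Ensembl genes, with a symbol, a description and a locus, and the tables list the same genes. A symbol was missing for 48 genes. All 3 value columns were used.

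FPKM is already divided by gene length and library size, so counts could not be tested, and values of different genes compare only as far as their gene models and mappability allow. Depth was inferred from single-exon genes, where a value is a whole multiple of what 1 fragment is worth if the gene length is the locus span. This gave 16550241, 15460924 and 17670986 fragments for animals 32, 39 and 68. At these depths 85.0, 86.6 and 82.0% of detected genes with spans up to 400 bases had values within 0.02 fragments of a whole number. Genes at 1 fragment that set the depth were not left out, so part of these shares is met by construction. Whole counts were not recovered for genes with several exons, whose lengths are not in the tables. Fragments from PCR are not independent molecules, so depth covers counting error only. FPKM sums were 479640, 472954 and 457994. No value above 0 was shared between libraries for the same gene, so each library was counted as a replicate. Without strand information, fragments of overlapping or antisense genes cannot be told apart, and near-identical copies (globins, ribosomal proteins, heat shock genes) are uncertain.

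All 3 animals form 1 group, so no comparison between groups, no pairing and no regrouping of samples was possible. Values were analysed as log2(FPKM + 0.1), and filters used a mean of at least 1 FPKM over the 3 animals. Gene pairs were tested with limma 3.58.1 in R 4.3.3 as a moderated one-sample test of the log2 ratio within each animal, with Benjamini-Hochberg adjustment over 54 pairs and a threshold of 0.05. An exact sign-flip test of 3 animals cannot go below p = 0.25 and was therefore not used. Variation between animals was tested in limma as the variance of a gene over the mean-dependent prior variance (an F test with trend, 13378 genes, prior degrees of freedom 2.54). For 45 of 47 lists, the root mean square deviation over animals was ranked among 10000 random lists of the same size drawn within 10 classes of mean expression. Lists needed 4 members past the filter. Of 622 listed symbols, 20 were not found in the tables, and 558 distinct genes were found, 10 of them with 2 gene IDs under 1 symbol, of which the ID with the higher mean was taken. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the rest.

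Each test was tested on simulated data. For 54 simulated pairs, all given the same spread, all 27 with a log2 ratio of 1 were recovered, with 1 false call. Real pairs had an SD of the log2 ratio from 0.057 to 2.44, so this recovery need not hold for them. Of 20 simulated lists of 12 members shifted by 0.5 on the log2 scale, 15 were recovered, with 0 false among 20 others. Simulated genes varied independently, so this gives no false rate for lists of co-expressed genes. The variance test, run on 13380 simulated genes, recovered 67.5% of 200 genes with a variance raised 100-fold when the simulated prior had 20 degrees of freedom, and 0% when it had the 2.54 estimated here.

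The gene lists, pairs, tests and alternatives were set before the data were examined. Named genes are the 25 with the highest mean FPKM, up to 24 pairs with the largest absolute log2 ratio with every pair that did not pass, the 25 with the lowest adjusted p of the variance test (ties by unadjusted p), and, per list, up to 4 members with the highest mean. Genes that fall outside this rule (Adora2a, Rgs9, list members named as listed at 0, pairs lost or gained when 1 animal was left out, and those in the closing observations) were chosen after their values were seen. Some genes and pairs that the rule names are not reported here, and counts and medians over lists or pairs include them. The count of pairs with both genes above 0 was added after the data were seen. Alternatives changed the pseudocount (1 or 0.01), the filter (none, or a mean of 5 FPKM), the scaling (equal totals, median of ratios or quantiles), the limma prior, the bound on the ratio and the list summary, and left out each animal in turn.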

Results

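The motor cortex of 3 untreated male Sprague-Dawley rats, an outbred laboratory stock, was profiled by sequencing of mRNA. The labels place all 3 animals (numbers 32, 39 and 68) in 1 group, called normal, at a time of 8 weeks, without saying whether this is an age or a time after another event. No treated group was analysed here. The data therefore answer what the dissected tissue expresses, how genes rank within it and how far the libraries of these untreated animals differ. With 1 library per animal, differences between animals, dissections and library preparations cannot be told apart. Values were deposited as FPKM (fragments counted per gene, divided by gene length and library size) for 30957 Ensembl genes in the Rnor_6.0 build of the rat genome. The depth was inferred as about 16550241, 15460924 and 17670986 fragments in animals 32, 39 and 68. With these depths, 85.0, 86.6 and 82.0% of detected genes with short loci had values within 0.02 fragments of a whole number. These shares include genes used to set the depth, so part of them is met by construction. A gene at 1 FPKM then rested on 16.6 ± 1.11 fragments per kilobase (SD, n = 3). Values below are mean ± SD over the 3 animals unless stated otherwise. The limma p-values concern only these 3 animals. For the gene pairs tested below they use a variance drawn towards that of all pairs (prior degrees of freedom 4.40).

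At least 1 FPKM was reached by 12585 genes in all 3 animals and by 13269 ± 292 genes per animal (SD, n = 3), while 12028 genes were listed at 0 in every library. Y-linked Eif2s3y (32.9 ± 1.98 FPKM), Ddx3y (25.4 ± 2.91) and Kdm5d (8.48 ± 0.435) were detected in every animal, all of which the labels give as male. Across the 13378 genes with a mean of at least 1 FPKM, log2 values of animals 32 and 39 correlated with a Pearson r of 0.979, those of 39 and 68 with 0.955 and those of 32 and 68 with 0.924. Spearman's rho was 0.984, 0.960 and 0.937 in the same order. These coefficients are across genes, which are not independent replicates. Differences above 2-fold were found for 420 genes between animals 32 and 39, for 822 between 39 and 68 and for 1715 between 32 and 68. The median gene had an SD of 0.20 on the log2 scale. With 1 animal left out it was 0.17 without animal 32, 0.22 without animal 39 and 0.11 without animal 68. Those values rest on a pair of animals each, so they are not strictly comparable with the SD over 3. Without animal 68 the lowest Pearson r was 0.979.

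Mitochondrially encoded transcripts headed the profile. Of the 25 genes with the highest mean, 15 lay on the mitochondrial genome, led by the cytochrome c oxidase subunit Mt-cox3 (MT, 8599 to 9382; 18026 ± 2879 FPKM), the ATP synthase subunit Mt-atp8 (17818 ± 2653) and the oxidase subunits Mt-co1 (16242 ± 2694) and Mt-co2 (12878 ± 2743). Mt-cytb (10275 ± 1734), Mt-nd2 (9777 ± 1397), Mt-nd1 (9214 ± 1562), Mt-nd4l (7194 ± 1218), Mt-atp6 (3680 ± 614), Mt-nd5 (3473 ± 572), Mt-nd3 (1993 ± 428) and Mt-nd4 (1890 ± 283) followed, with 3 mitochondrial genes listed as AY172581.9, AY172581.24 and AY172581.15 at 3023 ± 644, 2552 ± 678 and 963 ± 106 FPKM. Mt-atp8 and Mt-atp6 overlap in the annotation, as do Mt-nd4l and Mt-nd4, so the split of fragments within these pairs is uncertain. Mitochondrially encoded genes held 25.4 ± 3.62% of all FPKM, and the 10 highest genes of each animal held 23.4 ± 2.63%. Without mitochondrially encoded genes the 10 highest held 4.53 ± 1.58%.

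The 10 nuclear genes among the top 25 came from myelin, neurons and general cell functions. The myelin gene Mbp (chromosome 18, 79326738 to 79437310) stood at 2458 ± 1200 FPKM. Zwint, a kinetochore-associated protein, reached 1479 ± 99.2, the ferritin heavy chain Fth1 1379 ± 248, the calmodulin gene Calm3 1041 ± 131, beta-actin Actb 1008 ± 125, the protease inhibitor cystatin C (Cst3) 988 ± 176 and the synaptic fusion protein Snap25 954 ± 261. Ttr (transthyretin, a thyroid hormone carrier made in the choroid plexus; chromosome 18, 15532963 to 15540177) stood apart, at 8.36 FPKM in animal 32, 615 in animal 39 and 7264 in animal 68, and its place in the top 25 rests on animal 68.

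**Figure D1:**
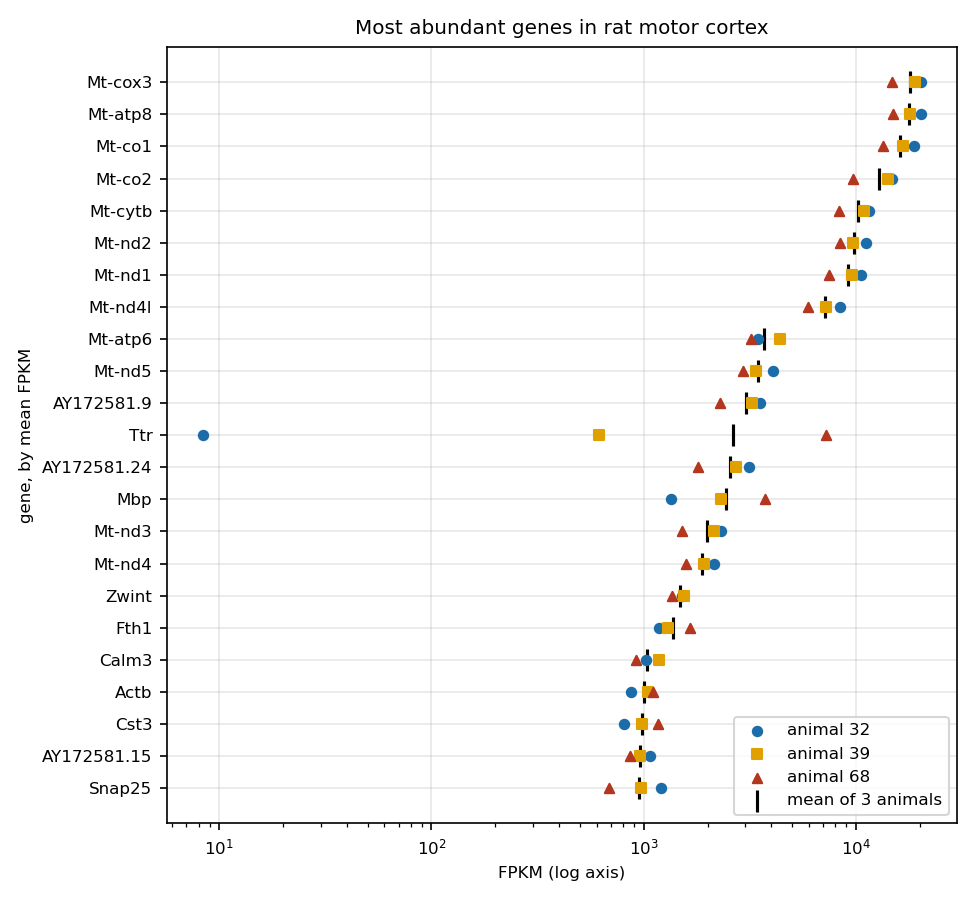
Genes among the 25 with the highest mean FPKM that are named in the text, with 1 point per animal on a log axis and a bar at the mean of the 3 animals. Ttr spans 8.36 to 7264 FPKM, and Mbp is highest in animal 68, while mitochondrial genes such as Mt-co1 (13376 to 18723) lie close together.

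Neuronal and glial markers were present at high levels in every animal. The median of the 12 pan-neuronal genes was 226 ± 38.9 FPKM, with Snap25, Thy1 (745 ± 135), Uchl1 (667 ± 52.0) and Syt1 (383 ± 44.4) highest. Glutamatergic neuron genes had a median of 94.6 ± 8.41, led by the calmodulin-binding protein Nrgn (813 ± 248), the kinase subunit Camk2a (685 ± 79.3) and the vesicular glutamate transporter Slc17a7 (517 ± 21.1). GABAergic neuron genes had a median of 26.2 ± 4.72, with Sst at 154 ± 46.4, Pvalb at 111 ± 38.6 and Lamp5 at 95.5 ± 49.6. Oligodendrocyte genes had a median of 194 ± 93.9, including Mbp, Cnp (391 ± 162) and Mobp (236 ± 124). Astrocyte genes had a median of 57.8 ± 24.8, with S100b (583 ± 188), the glutamine synthetase gene Glul (469 ± 76.2), Aldoc (225 ± 27.5) and Gfap (199 ± 135) highest. Oligodendrocyte precursor genes had a median of 15.7 ± 7.59 (Olig1 64.1 ± 25), microglial genes 9.07 ± 3.52 (C1qa 19.7 ± 7.65), endothelial genes 7.29 ± 0.737 (Itm2a 37.6 ± 6.11, Cldn5 35.5 ± 5.17) and mural cell genes of vessels 6.55 ± 1.43 (Rgs5 44.6 ± 5.21).

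Markers of upper and deep cortical layers were detected in every animal. The layer 5 list had all 12 of its genes at 1 FPKM or more in every animal and a median of 11.9 ± 2.76, with the calmodulin regulator Pcp4 at 185 ± 8.14, Crym at 84.5 ± 10.1, Sulf2 at 61.7 ± 18.6 and Etv1 at 15.4 ± 1.74. Fezf2, a transcription factor of deep-layer projection neurons, measured 13.9 ± 1.98. Upper-layer genes (layers 2 to 4) had a median of 6.77 ± 1.74, led by Lamp5, Wfs1 (89.3 ± 13.3), Calb1 (45.6 ± 26.0) and Mef2c (27.5 ± 16.6). Layer 6 genes had a median of 5.56 ± 1.06, with Tbr1 at 31.8 ± 14.4 and Rprm at 16.7 ± 5.68. Genes of corticospinal and other large projection neurons had a median of 21.2 ± 4.24, including Vamp1 (145 ± 22.7) and the neurofilament gene Nefh (46.4 ± 6.04). Among interneuron subclass genes (median 7.72 ± 0.709), the neuropeptide genes Cck (166 ± 65.8) and Sst were highest, and Npy was listed at 0 in all 3 libraries. Hprt1, Rpl8 and Rps6, which every cell uses, were also listed at 0, so such a value cannot be read as absence.

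Genes of other structures showed mixed levels. Of the 10 hypothalamic and basal forebrain genes, none reached 1 FPKM in all animals, and the median was 0.326 ± 0.177 (Hcrt 1.89 ± 1.16). Cerebellar and brainstem genes had a median of 0.0785 ± 0.0548 (0.0495 without animal 39), with Pcp2, Hoxb5, Hoxc5 and Slc6a3 listed at 0 and Car8 at 5.99 ± 0.841. The thalamic list had a median of 2.03 ± 0.479 (Ramp3 9.46 ± 2.14) and the hippocampal list 0.452 ± 0.269, where Wfs1 and Calb1 are shared with upper cortical layers. Striatal genes had medians of 2.45, 3.21 and 10.6 FPKM in animals 32, 39 and 68, with Ppp1r1b at 84.9 ± 42.4 and Penk at 23.5 ± 12.7. Choroid plexus genes had medians of 0.453, 2.95 and 39.8 in the same order, and ependymal genes 2.09, 2.84 and 7.34. Meningeal and fibroblast genes had a median of 4.44 ± 1.05, including Igf2 at 31.2 ± 29.6 and Dcn at 12.2 ± 4.26. Blood was represented by the globin genes Hba1 (425 ± 69.2), Hba2 (207 ± 30.2) and Hbb (144 ± 24); Hba1 and Hba2 are near-identical copies whose split is uncertain.

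Receptor and channel families were dominated by a few members. Among ionotropic glutamate receptors (median 10.9 ± 2.25), Gria2 (126 ± 16.8), Grin1 (99.7 ± 14.7), Gria3 (79.1 ± 20.6) and Gria1 (71.9 ± 15.4) were highest. GABA-A receptor subunits had a median of 16.2 ± 3.45. The metabotropic list had a median of 9.43 ± 3.04 (Grm5 18.5 ± 4.45, Grm3 17.6 ± 6.13). Sodium channel auxiliary subunits Scn3b (135 ± 38.1) and Scn2b (122 ± 10.3) exceeded the pore subunits Scn2a (46.4 ± 5.96) and Scn8a (39.5 ± 7.09) in level, with a list median of 9.83 ± 2.89. Potassium channels had a median of 18.1 ± 5.60, calcium channels 16.8 ± 2.05 (Cacnb3 79.7 ± 19.7), acetylcholine receptors 3.25 ± 0.519 (Chrm1 61.6 ± 11.6) and monoamine receptors 2.02 ± 0.427 (Adra1d 22.0 ± 1.02). Neuropeptide genes had a median of 6.08 ± 1.03, and neurotrophins with their receptors 2.59 ± 1.39 (Ntrk2 47.2 ± 12.5). Axon growth inhibitors and their receptors had a median of 24.6 ± 3.61, with Mag at 176 ± 78.5, Lingo1 at 122 ± 41.5, Omg at 118 ± 11.6 and Rtn4 at 95.7 ± 9.93. Perineuronal net and matrix genes had a median of 4.39 ± 1.98, with Hapln4 at 71.5 ± 8.89 and Bcan at 65.1 ± 23.1.

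Genes that report a tissue state were also quantified. Immediate early genes had a median of 11.3 ± 2.07 FPKM (Egr1 54.5 ± 7.36, Jun 25.3 ± 2.15, Arc 22.2 ± 10.6), clock genes 16.5 ± 2.43 (Tef 55.6 ± 2.07, Hlf 39.7 ± 16.8) and glucocorticoid-responsive genes 14.1 ± 3.70 (Mt2A 38.0 ± 4.74). Heat shock genes had a median of 5.70 ± 2.57, with the endoplasmic reticulum chaperone Hspa5 at 138 ± 52.8 and Hsph1 at 113 ± 5.67, while Hsp90aa1 and Hspa1a were listed at 0. Interferon-response genes (1.18 ± 0.550; Ifi27 43.2 ± 4.41), inflammation and gliosis genes (0.482 ± 0.151; Vim 50.5 ± 13.9) and cell cycle and neurogenesis genes (0.741 ± 0.327; Sox2 13.7 ± 4.77) had low medians. The 11 mitochondrially encoded list members had a median of 7194 ± 1218, glycolysis genes 192 ± 8.59 (Aldoa 845 ± 67.0), ribosomal protein genes 148 ± 13.7 (Rpsa 268 ± 29.5) and reference genes 178 ± 5.11 (Ywhaz 505 ± 36.9). A median of at least 1 FPKM in every animal was found for 40 of the 47 lists. With the mean of log2 values over members in place of the median, 24 list levels moved by more than their SD, such as that of GABA-A receptor subunits from 16.2 to 4.88 FPKM.

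Which member of a pair of related genes predominates in this tissue was tested for 54 pairs fixed before the data were examined. In 40 of the 53 pairs with both genes above 0 in some library, a choice made after seeing the data, the log2 ratio differed from 0 (limma, moderated one-sample test, Benjamini-Hochberg adjusted p under 0.05), and in 36 the ratio was above 2-fold. The count over all 54 was 41, where the added pair of Npy and Sst has its outcome fixed by the 0 listed for Npy. Slc17a7 exceeded Slc17a6, the other vesicular glutamate transporter, by 7.62 on the log2 scale (SE 0.36, n = 3; adjusted p = 5.29e-06; 517 ± 21.1 against 2.89 ± 1.84 FPKM). Snap25 exceeded its widely expressed relative Snap23 by 7.43 (SE 0.38; adjusted p = 5.29e-06), and hexokinase Hk1 exceeded Hk2 by 6.29 (SE 0.35; adjusted p = 8.03e-06). The matrix proteoglycan Bcan exceeded Acan 41.8-fold, and the obligatory NMDA receptor subunit Grin1 exceeded Grin2b 26.5-fold. Ratios were taken on FPKM plus 0.1, which understates those of low genes. They also depend on gene length and on how uniquely fragments map, errors that are shared by the 3 animals and not covered by the test.

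Other large ratios fell into neuronal, glial and metabolic families, all in the same direction in 3 of 3 animals. Syt1 exceeded Syt2 22.7-fold, the muscarinic receptor Chrm1 exceeded Chrm2 13.9-fold, Cck and Pvalb exceeded Vip 9.75-fold and 6.68-fold, the excitatory scaffold Dlg4 exceeded the inhibitory scaffold Gphn 9.32-fold and Nefl exceeded Nefh 5.62-fold. Egr1 exceeded Fos 7.47-fold and Ntrk2 exceeded Ntrk3 3.78-fold. The chloride exporter Slc12a5 exceeded the importer Slc12a2 4.22-fold (adjusted p = 0.00309, limma). Its log2 ratios were 2.94, 2.38 and 0.92 in animals 32, 39 and 68, so the fold differed widely between animals. In astrocytic families, Slc1a2 exceeded Slc1a3 5.64-fold and Gfap exceeded Aqp4 5.07-fold. In the opposite direction, Aldoa exceeded Aldoc 3.77-fold. Apoe exceeded Clu 3.26-fold. Slc2a1 measured 45.8 ± 10.3 FPKM against 0.238 ± 0.0344 for Slc2a3, a pair that passed the test but rests on a gene near 0, so no fold is given. Whether so low a level reflects the tissue or fragments lost in mapping was not tested. The pair is included in the counts of 40 pairs that passed and 36 above 2-fold. Without animal 39, 34 pairs passed, and the 7 that no longer did included Gria2 over Gria1, Gria2 over Gria3, Cacna1a over Cacna1b, Drd1 over Drd2 and Mag over Mog; Mag over Mog was also lost without either other animal, Gria2 over Gria1 without animal 32 and Gria2 over Gria3 without animal 68. Against a bound of 2-fold (limma treat), 24 pairs passed; these counts also include the pair of Npy and Sst.

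**Figure D2:**
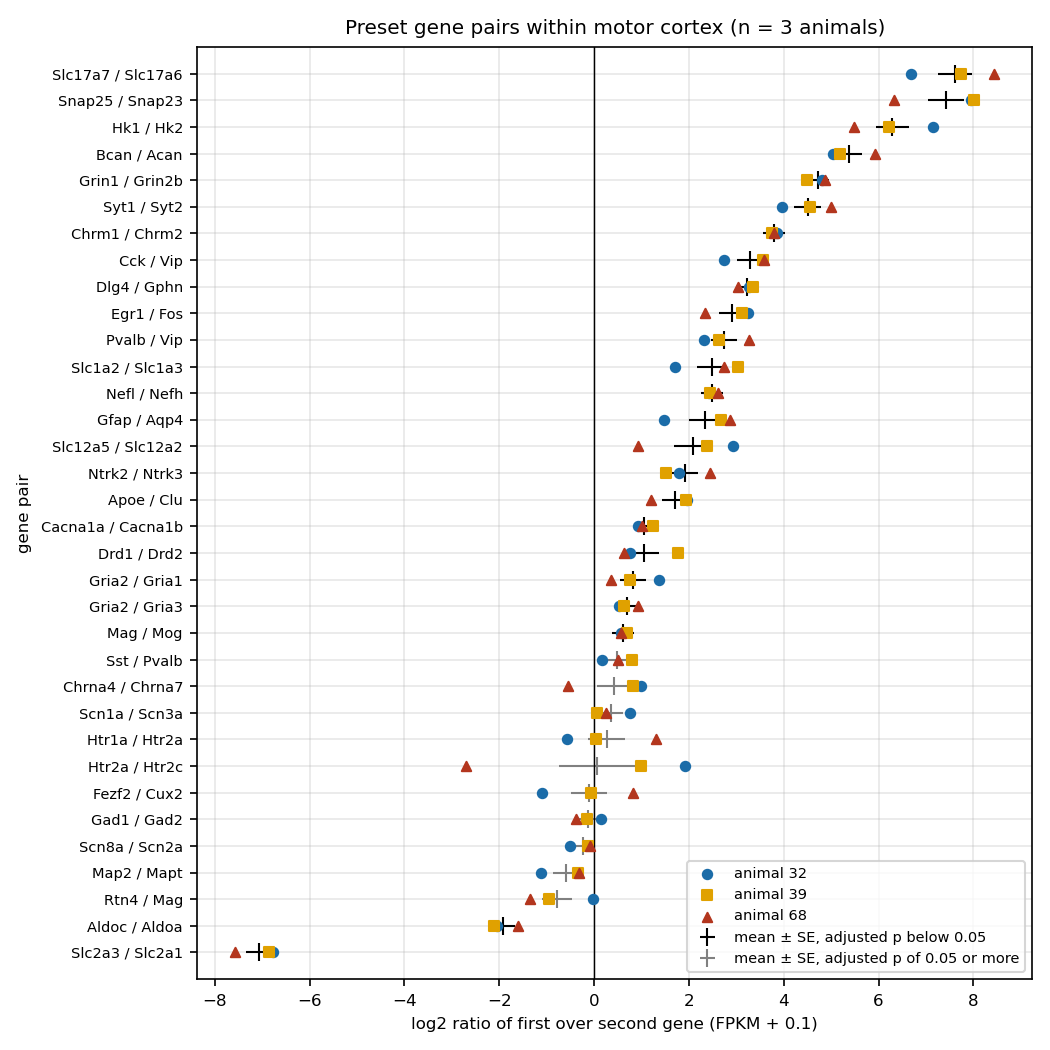
Log2 ratios of the preset gene pairs named in the text on FPKM plus 0.1, without the pair of Npy and Sst. Points are the 3 animals, and bars the mean ± SE of the limma test, black where the adjusted p was below 0.05; Slc17a7 over Slc17a6 (7.62) lies highest, and Slc2a3 over Slc2a1 rests on a gene near 0.

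In 13 pairs no difference passed the test. The levels of the GABA-synthesising enzymes Gad1 and Gad2 were 54.2 ± 12.1 and 58.1 ± 3.05 FPKM (adjusted p = 0.648, limma), and those of Scn8a and Scn2a had a log2 ratio of -0.24 (SE 0.23). Scn1a over Scn3a (0.36), Chrna4 over Chrna7 (0.42), Sst over Pvalb (0.49), Map2 over Mapt (-0.59) and Rtn4 over Mag (-0.78) did not pass either. For the cortical layer genes Fezf2 and Cux2, the animals differed in sign. Fezf2 over Cux2 was -1.09, -0.06 and 0.82, in animals 32, 39 and 68. The serotonin receptor ratio Htr2a over Htr2c ran from 1.91 in animal 32 to -2.70 in animal 68, and Htr1a over Htr2a from -0.56 to 1.31. Ttr, the choroid plexus marker, was 8.36, 615 and 7264 FPKM in the same animals. Pairs that passed the limma test without animal 68 included Htr2a over Htr2c (1.46), Chrna4 over Chrna7 (0.90) and Map2 over Mapt (-0.73), and Rtn4 over Mag (-1.16) passed without animal 32.

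Which genes varied between animals more than others of the same level was tested next. No gene passed (limma, SD against the mean-dependent trend, adjusted p under 0.05, 13378 genes tested). An unadjusted p under 0.05 in the same limma test was found for 687 genes where chance gives 669. The reference spread was fitted to these same genes, so a count near chance is largely built in. The 25 genes with the lowest p, all at an adjusted p of 0.878, were led by Ttr (SD 4.93 on the log2 scale). Ttr was followed by Mfrp (0.0674, 4.31 and 67.1 FPKM in animals 32, 39 and 68), the signalling inhibitor Sostdc1 (0.0685, 4.29 and 57.5), the ageing-related hormone co-receptor Kl (0.126, 2.66 and 58.0) and the chloride channel protein Clic6 (0.102, 2.95 and 51.0). Kl and Clic6 belong to the choroid plexus list with Ttr, as do Folr1 (0.453, 3.88 and 39.8), Enpp2 (49.3, 71.9 and 633), F5 (0.0576, 0.750 and 32.8) and Aqp1 (0.807, 1.63 and 25.6), which were also among the 25. Kcnj13, Mdk, Slc4a5, Calml4, Ace, Igfbp2, Tmem72, Msx1, Cfap126, Fam183b, Prr32, Igf2 (11.3, 17.1 and 65.2), Vat1l (13.2, 13.2 and 64.5) and Htr2c (2.69, 4.14 and 31.2) were also highest in animal 68. The metabotropic glutamate receptor gene Grm2 had the opposite order (22.7, 16.0 and 2.05), and LOC689986 was highest in animal 39 (1.81, 21.0 and 14.5). In data simulated with the estimated spread of variances, the test recovered 0% of 200 genes whose variance was raised 100-fold, so the count of 0 carries no information on stability. Without animal 68, Ttr alone passed (adjusted p = 0.00453, limma).

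Differences between animals were shared by members of several gene lists. For each of 45 lists with enough detected members, the joint deviation of its members in the 3 animals was set against 10000 random lists of the same size and mean level, as a description of these libraries. In 17 lists the deviation was one that under 2.5% of random lists reached, where 1.12 lists would be so by chance. Choroid plexus genes were 6.26 higher on the log2 scale in animal 68 than in animal 32, in 9 of 9 members. Ependymal genes were higher by 1.86 (4 of 4) and oligodendrocyte genes by 1.44 (12 of 12), with Mbp at 1341, 2305 and 3727 FPKM in animals 32, 39 and 68. Striatal genes were higher by 1.41 in 9 of 11 members, among them the receptor Adora2a (1.05, 1.35 and 11.2) and the signalling regulator Rgs9 (2.39, 3.15 and 18.2). Random lists do not share the co-expression of marker genes, and some lists share members, so the 17 lists are not independent.

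Other glial and state lists had the same direction. Animal 68 exceeded animal 32 by 1.24 for inflammation and gliosis genes (5 of the 6 tested), 1.09 for oligodendrocyte precursors (8 of 8), 1.07 for astrocytes (12 of 12), 1.05 for microglia (12 of 12), 0.97 for perineuronal net and matrix genes (9 of 9), 0.88 for meninges and fibroblasts (6 of 8), 0.77 for glucocorticoid-responsive genes (10 of 11) and 0.65 for heat shock genes (5 of 7). Astrocytic Slc1a2 measured 62.5, 177 and 299 FPKM and Gfap 97.3, 148 and 352 in animals 32, 39 and 68, next to 8.36, 615 and 7264 for Ttr. Gfap belongs to both the astrocyte and the gliosis list. Over all 15 gliosis genes found, most of them below the filter, the median had another order (0.652, 0.365 and 0.430 FPKM). The 4 tested members of the hippocampal list were highest in different animals: C1ql2 (2.04, 18.4 and 7.01) and Wfs1 in animal 39, Prox1 (2.71, 6.62 and 6.87) in animal 68 and Calb1 (72.8, 43.0 and 21.0) in animal 32.

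Lists of upper-layer and neuronal genes had the opposite direction. Upper-layer genes were lower in animal 68 than in animal 32 by a mean log2 difference of -1.06 (9 of 10 members), with Mef2c at 43.6, 28.4 and 10.5 FPKM, Cux2 at 27, 16.8 and 7.24 and Lamp5 at 139, 105 and 41.7 in animals 32, 39 and 68. Glutamatergic neuron genes differed by -0.64 (8 of 9 lower), interneuron subclass genes by -0.61 (8 of 14 lower; Vip 30.0, 17.6 and 7.44) and mitochondrially encoded genes by -0.44 (11 of 11 lower). Pan-neuronal genes (-0.34, 11 of 12 lower, 96.4th percentile) and GABAergic neuron genes (-0.37, 11 of 15 lower, 94.5th percentile) did not reach the bound. Both did with median-of-ratios scaling. Pan-neuronal genes also did with the median over members, and GABAergic neuron genes with a filter at a mean of 5 FPKM. Layer 5 genes, by contrast, had a mean difference of 0.00, within the range of random lists (50.9th percentile), as did endothelial genes (-0.10), glycolysis genes (-0.04), ribosomal protein genes (0.11) and reference genes (0.05); the sign for layer 5, glycolysis and reference genes depended on the scaling. In 15 of the 17 lists animal 39 lay between the others. Without animal 68, 11 lists passed the same bound, 8 of them among the 17; the upper-layer, ependymal, striatal, glutamatergic, interneuron, mitochondrial, gliosis, glucocorticoid and heat shock lists did not.

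**Figure D3:**
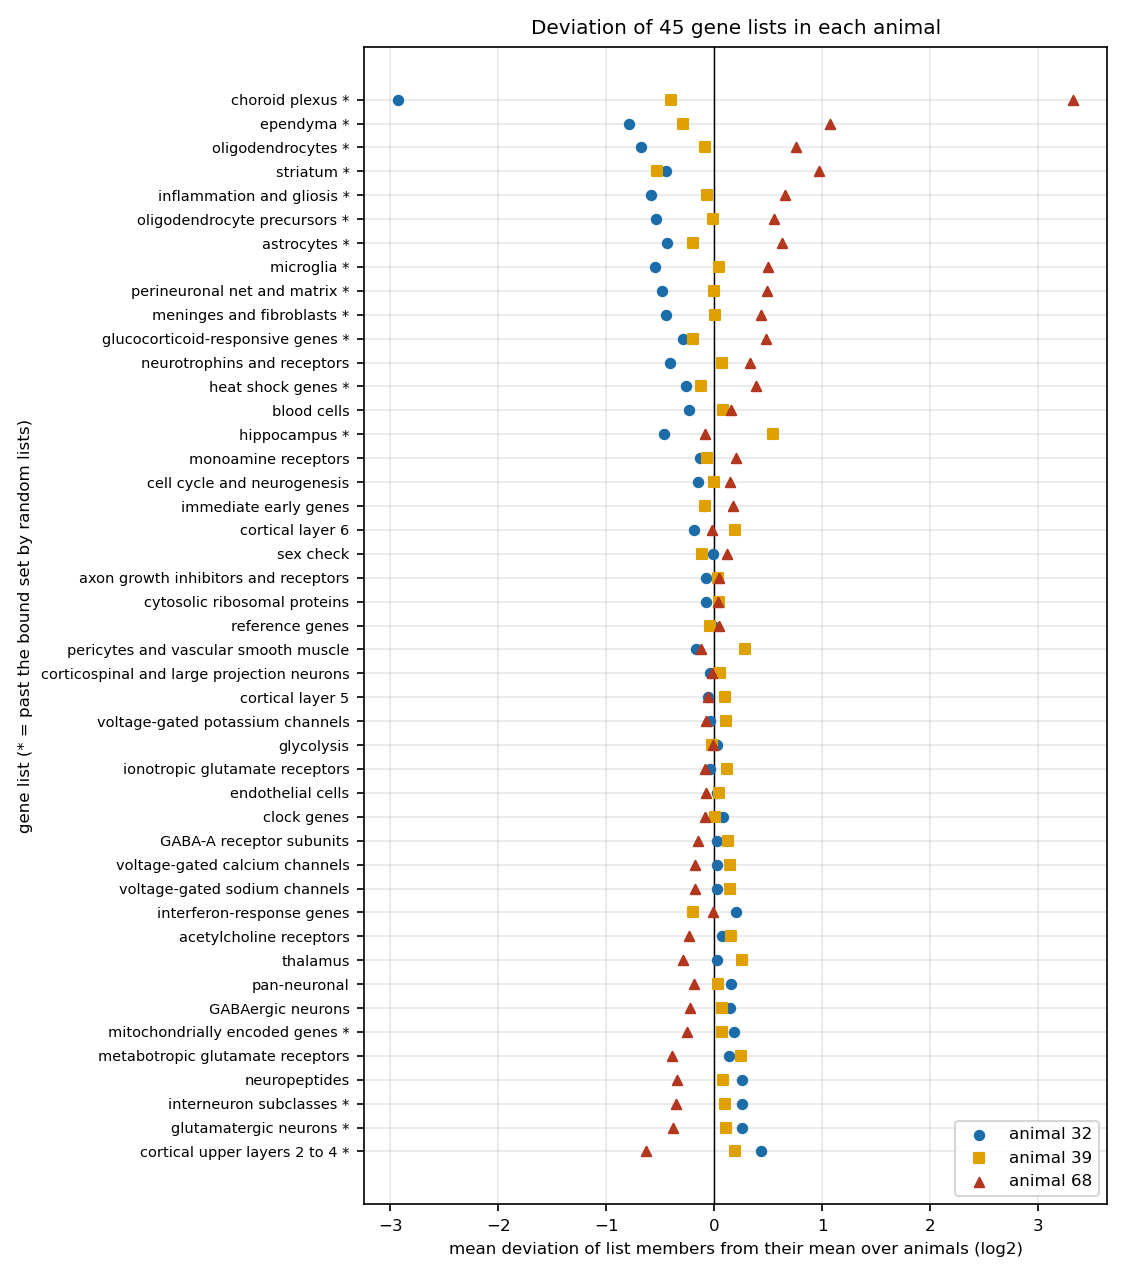
Mean log2 deviation of the members of each of 45 gene lists from their mean over the 3 animals, with 1 point per animal. Choroid plexus genes span -2.93 in animal 32 to 3.33 in animal 68, upper-layer genes have the opposite order (0.44 to -0.63), and layer 5 genes stay near 0; a star marks the 17 lists past the bound set by random lists.

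**Figure D4:**
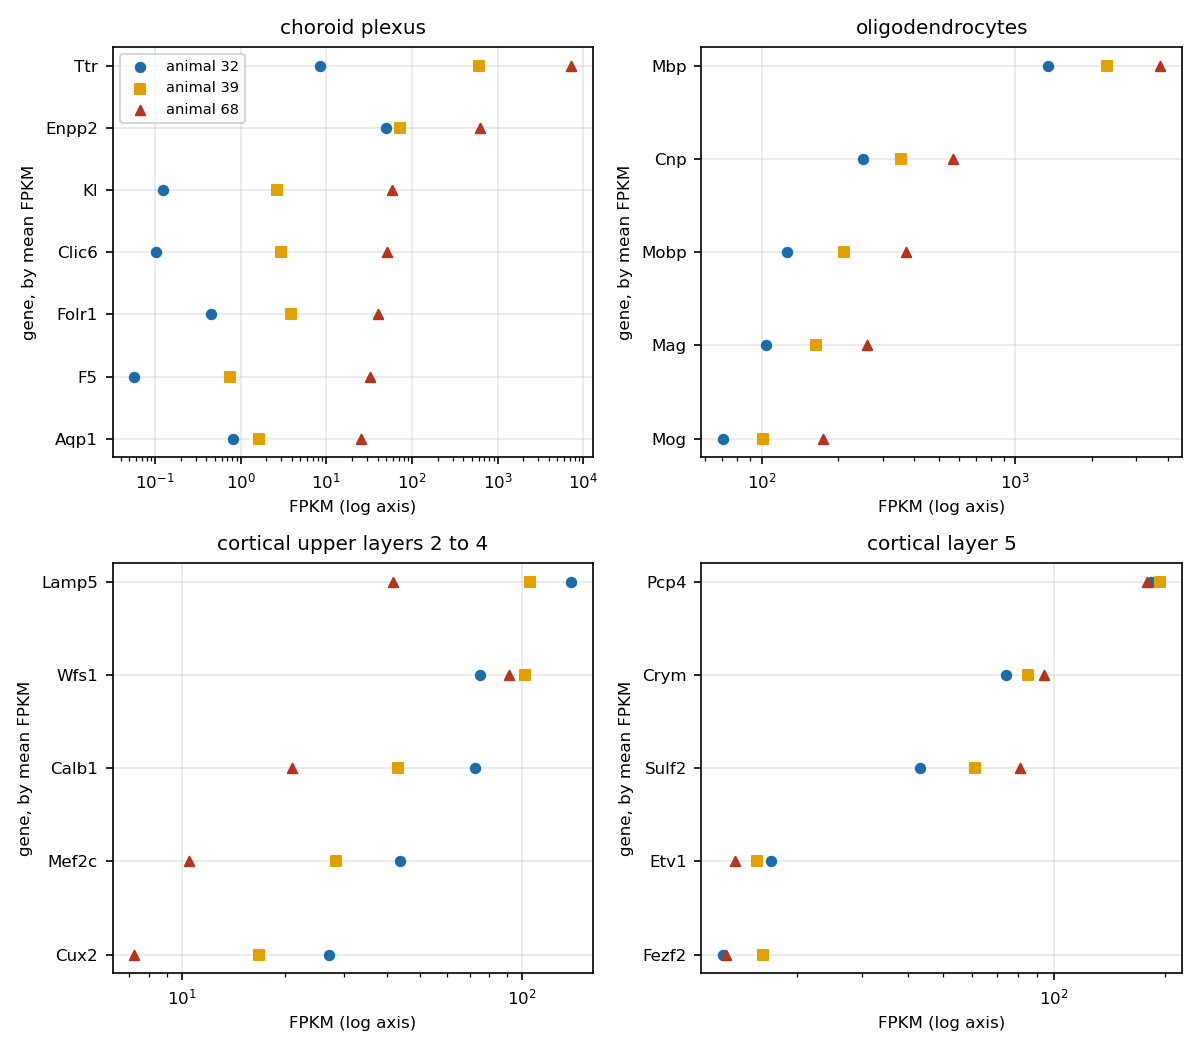
FPKM of genes of 4 lists that are named in the text, in each animal, on log axes. Choroid plexus and oligodendrocyte genes such as Mbp (1341, 2305 and 3727 in animals 32, 39 and 68) are highest in animal 68, most upper-layer genes such as Cux2 (27, 16.8 and 7.24) are lowest there, and layer 5 genes such as Pcp4 (185 ± 8.14) show no common order.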

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

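The lowest Pearson r between animals was 0.922 to 0.979 when 1 animal was left out and 0.955 without a filter, which adds low genes. Of the 54 pairs, 24 passed against a 2-fold bound, which asks for more than a difference from 0, and 34 to 42 passed without 1 animal. Genes past the variance test numbered 0 to 1 without 1 animal, the 1 being Ttr without animal 68, and 0 under the other settings. Lists past the random-list bound numbered 11 to 17 without 1 animal and 16 to 24 under other settings. Microglia and meninges were lost without animal 32, the hippocampal list without animal 39, and 9 lists without animal 68. Ependyma and gliosis were not tested with a mean of at least 5 FPKM, where 39 lists kept 4 members or more; all 17 were kept under pseudocount 1, median-of-ratios scaling and the median over members. The direction of animal 68 against animal 32 was the same for all 17 under the deposited, equal-total, median-of-ratios and quantile scalings. The share of the 10 highest genes was 4.53% without mitochondrially encoded genes, by construction. Counts of expressed genes and of lists with a median of at least 1 FPKM stayed within 1.5 times the reported ones.

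Pairs that did not pass changed sign in some settings, and the cause was not tested. Htr2a over Htr2c was -0.00029 with pseudocount 1 and -0.85 to 1.46 without 1 animal. In the same leave-one-out fits Gad1 over Gad2 was -0.26 to 0.0051, Htr1a over Htr2a -0.26 to 0.68 and Fezf2 over Cux2 -0.57 to 0.38. Depth limits genes near 1 FPKM, which rest on 16.6 ± 1.11 fragments per kilobase (SD, n = 3).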

Other observations

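The tests in this part were all chosen after the values they concern were seen. Differences of at least 4-fold between the highest and lowest animal were found for 332 of 13378 genes, and 267 of these were highest in animal 68, 43 in animal 32 and 22 in animal 39. Animal 39 lay between the others for 87.0% of the 332 genes and for 54.6% of all genes, where chance gives 33.3% for independent genes. Genes varied together between these animals, so the excess over 33.3% is a description and not a test of chance. Beyond the genes named above, the iron carrier Tf (168, 276 and 709 FPKM in animals 32, 39 and 68), the imprinted gene Nnat (45.2, 85.4 and 202) and the protease Klk6 (17.1, 30.9 and 71.9) were highest in animal 68. The G-protein regulator Rgs4 (293, 160 and 56.4), the synapse organiser Cbln2 (35.5, 25.1 and 8.63) and Dact2 (24.4, 14.2 and 3.40) had the opposite order.

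The 22 genes highest in animal 39 included C1ql2 (2.04, 18.4 and 7.01 FPKM in animals 32, 39 and 68), LOC689986 (1.81, 21.0 and 14.5), Usmg5 (1.71, 8.04 and 2.88), Fam210a (0.852, 5.85 and 0.934) and Sln (0.811, 4.99 and 1.71). C1ql2 is known from granule cells of the dentate gyrus. Prox1, a transcription factor of the same cells, measured 2.71, 6.62 and 6.87. No explanation was tested for the patterns of this and the preceding paragraph.

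Choroid plexus genes differed most between animals, with Ttr at 8.36, 615 and 7264 FPKM. A change of transthyretin alone within cortical cells is argued against, because the other 8 list members had a median log2 difference of 5.66 between animals 68 and 32 (range 3.05 to 8.01). Carry-over of fragments from animal 68 into the library of animal 39, as the whole cause, would give each gene the same share. That share is of the level in animal 68, above a baseline taken as animal 32. Its upper bound came from a 95% interval for counting error, with gene models of at least 1 kb assumed. This bound lay below the 8.36% of Ttr for 5 of the 8 other members. With no baseline taken off it did for 3 of 8, such as 6.22% for Kl. These bounds argue against carry-over as the whole cause, while carry-over as a part stays open. Choroid plexus tissue in the dissected block stays open: 9 of 9 members were highest in animal 68 and lowest in animal 32, but that count is the pattern itself and supports no cause over another. Carry-over from a sample not analysed here stays open too.

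Upper-layer genes were lower and glial genes higher in animal 68. Dilution of cortex by tissue without neurons, as the whole cause, would lower upper-layer and layer 5 genes alike if that tissue expressed neither. The upper-layer minus the layer 5 difference was -1.06 on the log2 scale, a gap that a share of 0.0029 of random splits of the members reached. Both list differences had already been seen, and the splits treat co-expressed genes as independent, so the share is only a description. The gap argues against dilution as the whole cause only under the assumption on the added tissue. Dilution as a part stays open, with pan-neuronal genes at -0.343 (11 of 12 lower) and GABAergic neuron genes at -0.374 (11 of 15 lower). A bias with locus length as the whole cause is argued against, since its class medians ran only from 0.0201 to 0.174. With those of 10 locus-length by 5 level classes removed, the gap was -1.09 (share 0.0029, again only a description). A block that reached deeper structures is a candidate explanation. The striatal list was 1.41 higher in animal 68, but this was already seen when the explanation was put forward, so it is no independent support. Some layer 5 genes are also expressed in striatum, and 2 of 11 striatal members had the other direction. The thalamic list was lower by 0.318 (6 of 7 members), within the range of random lists (72.8th percentile). A bias with transcript length, which is not in the tables, and a real difference between the cortices of these animals stay open.

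Several genes known from cortex or from cells in general were listed at 0 in all libraries, namely Npy, Rpl8, Rps6, Hprt1, Hsp90aa1 and Col1a2. Overlap with another gene model is argued against as the common cause, since 1 of the 6 overlapped one. Fragments lost to near-identical copies are a candidate explanation: of 258 gene IDs that share a symbol and chromosome with another, 65.1% were listed at 0, against 10.2% of 15744 with a symbol of their own (Fisher's exact test, two-sided, p = 1.48e-97; receptor and placeholder families left out, 73.1% against 19.8% with them). Npy (chromosome 4, 79557854 to 79565097) has a like-named neighbour at 79573998 to 79581208, Rps6 has one on chromosome 5 and Hprt1 a second ID on chromosome X, all at 0, while of the 2 like-named genes of Rpl8, LOC100910370 is at 0 and LOC100360117 at 179, 183 and 182 FPKM. Of the 6 genes, only Hprt1 has a second ID under its own symbol, so the Fisher comparison does not cover the others directly. IDs that share a symbol are not independent, and silent copies would also raise that share. Col1a2 and Hsp90aa1 have no such copy among the listed genes.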
